A study of Mus musculus with 13 samples.

How the data were processed

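Gene expression was measured by bulk RNA sequencing in cells sorted by fluorescence from dorsal root ganglia (DRG) of adult mice at 3 months of age. The mice were C57BL/6 heterozygotes with enhanced green fluorescent protein (EGFP) at the locus of Ret, the receptor tyrosine kinase of the glial cell line-derived neurotrophic factor (GDNF) family, so that EGFP marks cells that express Ret. Per the labels, ganglia came from spinal levels L6 and S1 (L6S1) or from L3, L4 and L5 (L345) of females or males. The 13 libraries fall into 4 groups: 3 from female L345, 3 from female L6S1, 3 from male L345 and 4 from male L6S1. Each library is a pool of 2 to 9 mice, 61 mice in all if no mouse gave ganglia to both levels, which the labels do not state. Libraries were made from 10 ng of total RNA with a SMARTer Ultra Low Input kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols.

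The deposited files hold, for each of 41388 genes with an Ensembl identifier, a count of reads, a CPM value and an RPKM value. The submitters' processing notes name STAR 2.0.4b, Subread, featureCounts 1.4.5, Salmon and the builds GRCm38.p2 and mm10, without the role or order of each. How reads that map to several genes were handled and whether strand was used are not given in the sources used here. The counts that the authors deposited are whole numbers with no normalization, and they were the input of every test. The CPM that the authors deposited equals the count divided by the library's own total, in the unit its name gives, with no factor between libraries, and recomputing it left a largest relative difference of 5.10e-15. The deposited RPKM equals that CPM per kilobase of the gene length in the file, with a largest relative difference of 5.21e-14. Both columns served only as a check of the counts, and CPM printed here is the count over the library's total times its TMM factor, scaled in the same way. The TMM factor was 0.796 in male L6S1 E, 0.925 in male L6S1 D and 1.01 to 1.05 in the other 11 libraries, so that CPM printed for D and E lies above the deposited CPM. Total counts ran from 13030096 to 27011995 per library, so that a floor of 3 counts is 0.111 to 0.230 CPM before the TMM factor. Such floors allow for counting error alone and not for the spread between pools, while SDs of low counts hold both. Amplified reads without molecular identifiers are not independent molecules. Gene symbols and coordinates came from GENCODE M21 on GRCm38, the build of the files, in which 40254 identifiers matched a symbol and 1134 did not. The unmatched ones held 0.109% of all counts. Because strand handling is not given, a gene and an antisense partner cannot be separated, and counts of near-identical copies may be split.

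All tests used R 4.3.3. Genes were filtered with filterByExpr, which left 15406, scaled with TMM factors and tested with the robust quasi-likelihood F-test of edgeR 4.0.16, with 1 mean per group over all 13 libraries and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. The comparisons were L6S1 against L345 averaged over the sexes, in females and in males, the difference of that effect between the sexes, and males against females averaged over the levels, at L6S1 and at L345. Log2 fold changes are given with a standard error (SE) and CPM as mean ± SD over the libraries of a group. This SE was derived as the absolute log2 fold change over the square root of its F statistic, not estimated by the fit itself. The 35 gene lists were fixed before the data were examined, as were the groups, the tests and most alternatives. The 34 with at least 3 tested members were tested with camera of limma 3.58.1, which compares a list with all other genes, at a preset correlation of 0.01 between genes and with adjustment over the lists. Camera with an estimated correlation, and fry, which tests whether a list moves on balance without comparing it with other genes, were alternatives. The lists cover Hox genes, sensory neuron transcription factors, markers of sensory neuron types and of other cell types, stress and injury genes, ion channels, receptors, neuropeptides, guidance molecules, sex-linked genes, and mitochondrial and ribosomal genes.

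Genes named in the text followed a rule. It took for each comparison the 10 largest changes in each direction among called genes with a mean log2 CPM of at least 1, without predicted genes and immunoglobulin or T cell receptor segments, and at most 6 per direction in the smaller comparisons. It added up to 4 called members of each list and, where fewer than 5 genes passed, the 5 smallest p. Ret, Gfra1, Gfra2, Gfra3, Mrgprd, Calca, Nefh, Th and Apoe were always named, and Xist, Ddx3y, Uty, Kdm5d and Eif2s3y for the sexes. Some genes that the rule or the tests cover are not reported here. Members of a list that passed only when adjusted over the list alone are named as examples and were chosen after their values were seen, as were Trac, Igha and Blnk.

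Alternatives were RLE size factors, DESeq2 1.42.0, limma voom with sample quality weights, no filter, a filter of at least 1 CPM in at least 6 libraries, a fold of at least 2, fits on the 2 groups compared alone, leaving out each library in turn, leaving out male L6S1 E and F, whose labels follow another form, and the replicate letter as a block. A correction for gene length and GC content, leaving out male L6S1 D and E, and blocked and leave-one-out list tests were added after seeing the data. The replicate letters are not explained in the labels. Libraries of 1 letter deviated together from their group means, with correlations across the levels in females of 0.520 for A, 0.203 for B and 0.488 for C and across the sexes at L345 of 0.505, 0.221 and 0.349. Each is over 0.1, so the letters were taken to pair the libraries in the block, although each B library correlated as well with another letter, at 0.252 and 0.268. The block was an alternative only. The main tests used 1 mean per group without pairs, so their p-values take no account of this pairing. In males the levels share only the letter A, at 0.101. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, the main test recovered 44% and 99% for the level averaged over the sexes, 7% and 86% in females, 16% and 88% in males, 0% and 25% for the difference between the sexes, and 55% and 100% for sex averaged over the levels. It recovered 9% and 89% for sex at L6S1 and 7% and 83% for sex at L345. These ran on 15123 to 15148 genes, and 4.67% of the calls of the averaged level comparison were false. For that comparison 16.1% of the calls of DESeq2 were false, with 62% and 99% recovered, and 8.47% of those with the replicate block, with 13% and 95% recovered. The simulated libraries were independent, with the same spread in every group, no pairing by letter and no library apart from the others. Changed genes had a mean log2 CPM over 1. These rates therefore need not hold for the real libraries or rank the methods on them.

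The labels come in 3 forms, 1 for all females, 1 for most males and 1 for male L6S1 E and F, so that sex cannot be separated from whatever differs between these sets of labels, and no batch or date is given. Replicates of a group are separately labelled pools of mice, and p-values measure the spread between pools. That spread was estimated jointly over the 4 groups and without the replicate letters, so a comparison of 2 groups also borrows the spread of the others. Fits on the 2 groups alone gave 14 genes against 3 for the levels in females and 2 against 34 in males.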

Results

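Expression of 41388 genes was measured in Ret-positive cells sorted from mouse dorsal root ganglia at 2 spinal levels in females and males. The groups held 3 libraries of female L345, 3 of female L6S1, 3 of male L345 and 4 of male L6S1. The total counts per library in this order were 18437222 to 23827169, 15826788 to 22175610, 13030096 to 21104274 and 21471328 to 27011995. Of all genes, 26901 had at least 1 count and 15406 passed the filter and were tested. The first principal component of log2 CPM held 40.8% of the variance and the second 20.5%. Male L6S1 replicates D and E lay apart from the other 11 libraries on the first, by 2.75 and 5.29 SDs of those libraries. On the second, the A replicates of the other 3 groups were highest, at 39.0 to 62.4, and male L6S1 F was lowest, at -52.9. Ret itself (ENSMUSG00000030110, chromosome 6, 118151748 to 118197744 on GRCm38) was expressed in every library, at 203 ± 3.62 CPM (SD, n = 3) in female L345 and 182 ± 0.866 CPM (n = 3) in female L6S1. In males it was at 201 ± 5.78 CPM (n = 3) in male L345 and 165 ± 58.5 CPM (n = 4) in male L6S1. Its lowest value, 87.3 CPM, was in male L6S1 E.

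**Figure D1:**
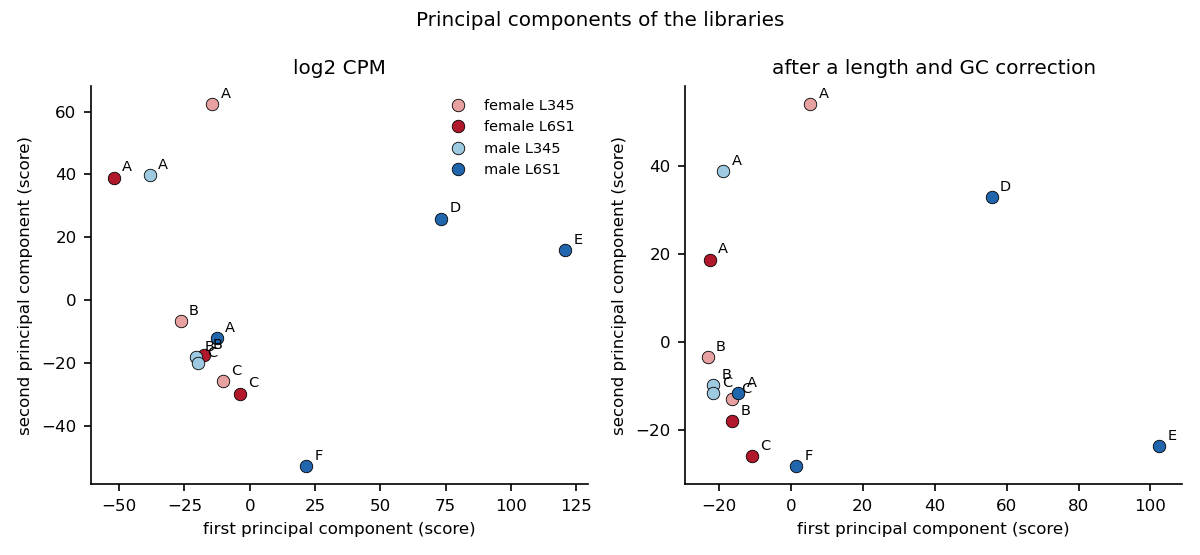
Each point is a library placed by its first and second principal component of log2 CPM, which hold 40.8% and 20.5% of the variance, and colours mark the 4 groups. Male L6S1 D and E lie apart from the other 11 libraries on the first component.

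The comparison of spinal levels asked how Ret-positive neurons of L6S1 ganglia, through which many pelvic visceral afferents run, differ from those of L345 ganglia, which mainly serve the hindlimb. Averaged over the sexes, 69 of 15406 genes passed, 66 higher at L6S1 and 3 lower, and 65 of them changed at least 2-fold. With the replicate letter as a block 90 passed, 73 higher and 17 lower, 49 of them shared with these 69. In this comparison the block rests on 4 pairs of libraries, those of female A, B and C and of male A, so its values weigh females more than the average does. The block fit left only 3 residual degrees of freedom per gene. Lower genes were more numerous in other fits, with 164 higher and 23 lower by DESeq2, which had 26884 genes and its own filtering, 132 and 12 by edgeR without the low-count filter, 234 and 80 by limma voom and 109 and 51 with the block and the length and GC correction. The genes that rose included posterior Hox genes, which encode positional identity along the body axis, and the noncoding RNA Hotair. Also higher were the nicotinic acetylcholine receptor subunits Chrna3 and Chrnb4, the serotonin-gated channel subunit Htr3a, several neuropeptide precursors, the estrogen receptor Esr1 and the background potassium channels Kcnk2 and Kcnk3. Anterior Hox genes of the B cluster fell.

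Hoxc11 (ENSMUSG00000001656, chromosome 15, 102954427 to 102957708) was at most 0.205 CPM in the 6 L345 libraries and at least 2.14 CPM in the 7 L6S1 libraries (adjusted p = 2.23e-05). Hotair (ENSMUSG00000086903, chromosome 15, 102944062 to 102947730), a long noncoding RNA of the same cluster whose exons do not overlap those of Hoxc11, rose 25.4-fold. This was a log2 fold change of 4.66 (SE 0.46, adjusted p = 1.32e-04, higher in 7 of 7 L6S1 libraries than in any L345 library). Hoxd11 (ENSMUSG00000042499, chromosome 2, 74679557 to 74687016) rose from 3.27 ± 1.45 to 24.2 ± 5.73 CPM in females (n = 3 and 3) and from 2.46 ± 1.84 to 21.8 ± 3.00 CPM in males (n = 3 and 4), with an adjusted p of 5.50e-04. Hoxd10 (ENSMUSG00000050368, chromosome 2, 74691924 to 74695105) rose by 2.94 on the log2 scale (SE 0.35, adjusted p = 5.50e-04) and Hoxd9 by 1.90 (SE 0.24, adjusted p = 9.87e-04), each in 7 of 7 libraries. Hoxc10, which shares 8.70% of its exon bases with Hoxc5 on the same strand, rose by 0.94 (SE 0.18, adjusted p = 0.0234). Hoxb5 (ENSMUSG00000038700, chromosome 11, 96303336 to 96306121) fell from 37.2 ± 4.69 to 14.4 ± 3.54 CPM in females and from 35.8 ± 5.11 to 21.6 ± 6.27 CPM in males, a log2 fold change of -1.05 (SE 0.20, adjusted p = 0.0283, lower in 7 of 7). Hoxb6 changed by -1.76 (SE 0.36, adjusted p = 0.0381, lower in 6 of 7). Of 17 tested genes of Hox groups 1 to 8, 2 fell over all genes and 7 adjusted over the list alone, among them Hoxb7 (-1.84, SE 0.41) and Hoxc6 (-1.13, SE 0.26). The list fell by camera (median -0.57, adjusted p = 4.65e-08, and adjusted p = 0.0279 with an estimated correlation). With the replicate block and an estimated correlation the call ended (adjusted p = 0.272). Of the 7 genes of Hox groups 9 and 10, 3 rose and 4 did not pass. The median of that list was -0.14, its mean 0.60, and camera gave a higher list (adjusted p = 0.0199, and adjusted p = 0.337 with an estimated correlation). Its adjusted p was 0.146 with the replicate letter as a block. The 2 tested members of Hox groups 11 to 13 both rose, too few for a list test.

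**Figure D2:**
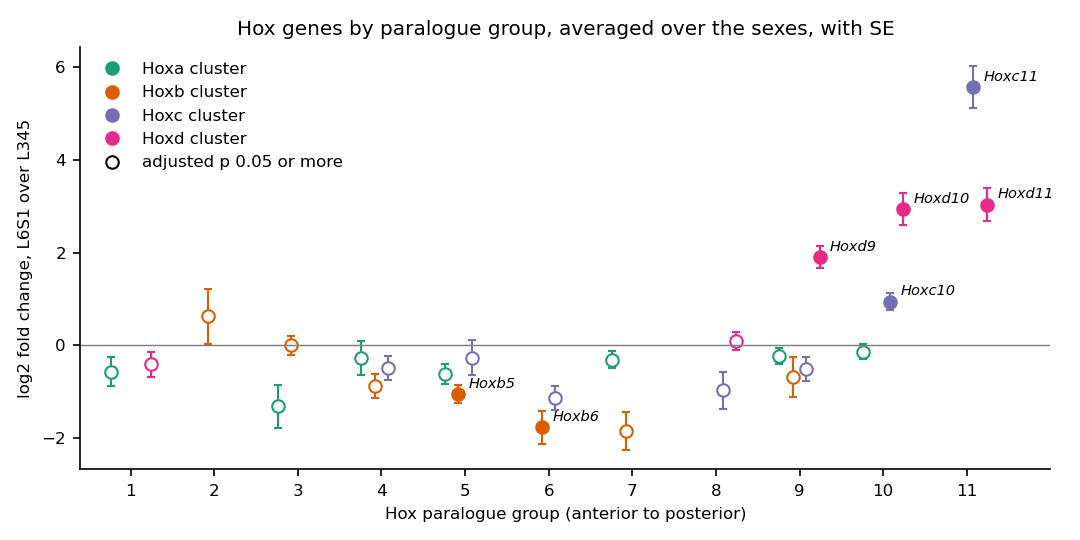
Points give the log2 fold change of each tested Hox gene, L6S1 against L345 averaged over the sexes, by paralogue group, with bars for the SE. Filled points mark genes with an adjusted p under 0.05, and colours mark the Hox clusters. In single libraries, which the plot does not show, Hoxc11 and Hoxd11 are higher in all 7 of L6S1 than in any of L345, and Hoxb5 is lower in all 7.

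Receptors and channels that rose at L6S1 included Chrna3 (ENSMUSG00000032303, chromosome 9, 55011343 to 55026559), which went from 5.58 ± 3.11 to 81.5 ± 23.2 CPM in females and from 4.49 ± 0.364 to 31.8 ± 23.8 CPM in males. The log2 fold change was 3.34 (SE 0.38, adjusted p = 4.14e-04, higher in 7 of 7). Its neighbour Chrnb4 (ENSMUSG00000035200, 55028156 to 55048544) rose by 2.19 (SE 0.31, adjusted p = 0.00287, 7 of 7). Of genes that autonomic neurons express, Phox2a, Hand2, Dbh and Slc6a2 together stayed at or below 0.424 CPM in every library. Htr3a rose from 37.5 ± 15.2 to 111 ± 32.0 CPM in females and from 34.9 ± 3.71 to 100.0 ± 41.3 CPM in males (log2 fold change 1.54, SE 0.27, adjusted p = 0.0160, 7 of 7). Of 32 tested opioid, serotonin, cholinergic, adrenergic and cannabinoid receptors, these 3 rose, over all genes and adjusted over the list alone, and the list did not pass (median -0.01, mean 0.20, adjusted p = 0.290), although it did with the replicate block (adjusted p = 1.39e-04, and adjusted p = 0.384 with the block and an estimated correlation). Of 68 potassium and HCN channels, Kcnk3 (1.22, SE 0.23, adjusted p = 0.0234, 7 of 7) and Kcnk2 (1.46, SE 0.30, adjusted p = 0.0410, 6 of 7) rose. Adjusted over the list alone 3 were higher and 1 lower, and the list did not pass (median -0.06, mean 0.02, adjusted p = 0.290). Esr1 (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614) rose from 13.3 ± 3.23 to 58.0 ± 15.0 CPM in females and from 11.3 ± 5.06 to 20.6 ± 7.52 CPM in males (2.82-fold, adjusted p = 0.0141, 6 of 7). The progesterone receptor Pgr passed adjusted over the list alone (1.54, SE 0.38), and the 17 steroid and peptide hormone receptors did not pass as a list (median 0.07, adjusted p = 0.589) except with the replicate block (adjusted p = 0.0227, and adjusted p = 0.367 with the block and an estimated correlation). With that block the adjusted p of Esr1 was 0.0688, in a range of 9.09e-06 to 0.0716 over all alternatives.

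Neuropeptides rose as a list of 20 (median 0.41, adjusted p = 3.12e-05, and adjusted p = 0.337 with an estimated correlation), with 4 higher over all genes, and 5 higher and 2 lower adjusted over the list alone. Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), the enkephalin precursor, rose from 15.1 ± 2.56 to 46.2 ± 19.9 CPM in females and from 22.1 ± 9.85 to 272 ± 213 CPM in males (log2 fold change 2.61, SE 0.41, adjusted p = 0.00667, 7 of 7). Male L6S1 D and E held 322 and 552 CPM of Penk, A and F 86.8 and 126 CPM, and neuropeptides as a list lay a median 1.21 and 1.32 on the log2 scale above the other 11 libraries in D and E. Cartpt, the precursor of the CART peptides, rose by 1.49 (SE 0.28, adjusted p = 0.0272, 7 of 7). The synaptic organizer Cbln1 rose by 1.91 (SE 0.33, adjusted p = 0.0141, 7 of 7) and Uts2b, a urotensin precursor, by 3.53 (SE 0.68, adjusted p = 0.0283, 5 of 7). With the replicate block Cbln1 had an adjusted p of 0.0588 and Uts2b of 0.0615, in ranges of 1.89e-05 to 0.0829 and 4.64e-04 to 0.206 over all alternatives. The dynorphin precursor Pdyn fell adjusted over the list alone (-1.21, SE 0.37). Adm, which encodes the vasodilator adrenomedullin, rose by 3.01 (SE 0.36, adjusted p = 6.16e-04, 7 of 7). Srd5a2 (ENSMUSG00000038541, chromosome 17, 74017706 to 74047916), whose product turns testosterone into dihydrotestosterone, rose by 3.58 (SE 0.55, adjusted p = 0.00590, 5 of 7), to 1.07 ± 0.115 CPM in females and 7.24 ± 4.12 CPM in males. The glutathione transferase Gsta4 rose by 2.31 (SE 0.35, adjusted p = 0.00590, 7 of 7), and D and E held 156 and 211 CPM against at most 55.2 CPM in the other libraries of L6S1. Arap3 rose by 2.36 (SE 0.47, adjusted p = 0.0374), and Fbp1, an enzyme of gluconeogenesis, changed by -1.58 (SE 0.32, adjusted p = 0.0373, lower in 6 of 7).

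**Figure D3:**
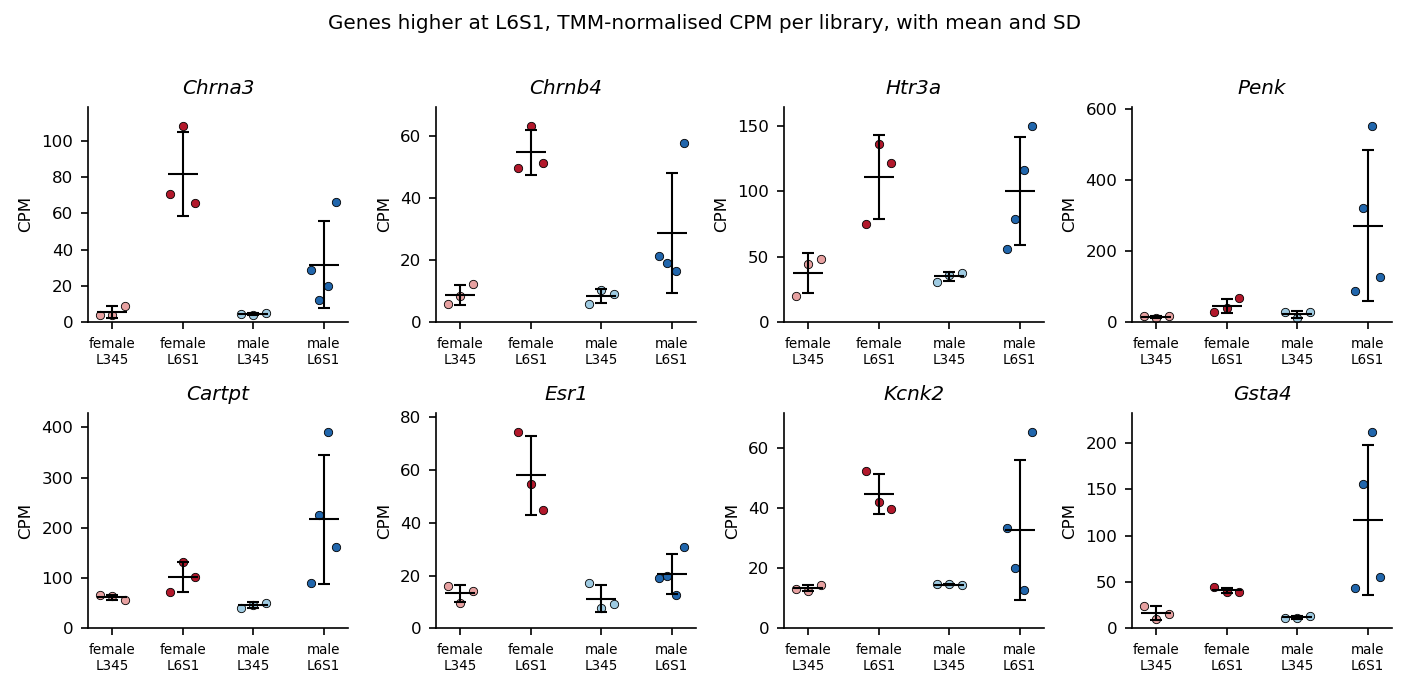
The plot shows CPM of Chrna3, Chrnb4, Htr3a, Penk, Cartpt, Esr1, Kcnk2 and Gsta4 in each library by sex and spinal level, with bars for the mean and SD of 3 or 4 libraries. In male L6S1 the highest values of Penk, 322 and 552 CPM, belong to D and E, and the highest value of Chrna3, 66.1 CPM, belongs to F.

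Among markers of sensory neuron types, the 19 peptidergic nociceptor markers rose as a list (median 0.34, adjusted p = 0.00401, and adjusted p = 0.202 with an estimated correlation). Gal (1.30, SE 0.29) and Gfra3 (0.58, SE 0.19) were higher and Rab27b and Prokr2 lower adjusted over the list alone, and none was called over all genes. The 28 nonpeptidergic markers fell (median -0.19, adjusted p = 0.00591, and adjusted p = 0.569 with an estimated correlation) with no member passing either way, and the call ended with the replicate block (adjusted p = 0.757). D and E lay a median -0.59 and -1.04 from the other libraries in this list. The 10 C low-threshold mechanoreceptor markers fell (median -0.40, adjusted p = 0.00216, and adjusted p = 0.348 with an estimated correlation), with Piezo2 (-0.67, SE 0.21) and Pou4f2 (-0.75, SE 0.24) lower adjusted over the list alone. D and E lay -0.94 and -1.26 from the other libraries. The 6 cold-sensing neuron markers rose (median 0.59, adjusted p = 0.00357, and adjusted p = 0.258 with an estimated correlation). Penk was called, and the menthol receptor Trpm8 (0.93, SE 0.24) and Gpr26 (0.66, SE 0.27) also passed adjusted over the list alone. The 10 pruriceptor markers rose (median 0.29, adjusted p = 0.00872, and adjusted p = 0.348 with an estimated correlation). The 32 sensory neuron transcription factors fell (median -0.21, adjusted p = 0.00252, and adjusted p = 0.258 with an estimated correlation), with Bcl11b (-0.66, SE 0.17) lower and Pou4f3 (0.72, SE 0.17) higher adjusted over the list alone. The 28 A-fibre mechanoreceptor markers (adjusted p = 0.166) and the 10 proprioceptor markers (adjusted p = 0.805) did not pass. Single markers did not pass either, with log2 fold changes of -0.23 for Ret (adjusted p = 0.708), -0.29 for Gfra1 (0.749), -0.41 for Gfra2 (0.666), 0.58 for Gfra3 (0.357), -0.42 for Mrgprd (0.675), 0.46 for Calca (0.597), 0.11 for Nefh (0.871) and 0.13 for Th (0.790).

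Markers of other cells moved in both directions. The 25 satellite glia and Schwann cell markers fell (median -0.42, adjusted p = 1.24e-04, and adjusted p = 0.258 with an estimated correlation), with Mbp (-0.82, SE 0.22) and Erbb3 (-0.72, SE 0.19) lower adjusted over the list alone. Apoe had a log2 fold change of 0.77 and did not pass (adjusted p = 0.609). The 12 immune markers rose (median 0.35, adjusted p = 0.0486, and adjusted p = 0.543 with an estimated correlation) and D and E lay 1.42 and 1.64 above the other libraries. With the replicate block this list pointed the other way without passing (adjusted p = 0.621). C1qb, a complement subunit, rose by 2.18 (SE 0.34, adjusted p = 0.00667, 7 of 7, and 0.0535 with the block and the length and GC correction), while C1qa and C1qc, whose products assemble with it, held 19 counts in all libraries together against 871 of C1qb. The 11 sympathetic neuron markers rose (median 0.17, adjusted p = 0.0483, and adjusted p = 0.258 with an estimated correlation), the members that passed being Chrna3 and Chrnb4. The 5 skeletal muscle markers rose (median 0.36, adjusted p = 0.0480, adjusted p = 0.337 with an estimated correlation, 0.722 in the other direction with the replicate block). The 15 fibroblast markers did not pass (median -0.02, test higher, adjusted p = 0.793), with Dcn (1.19) and Col6a2 (0.96) higher adjusted over the list alone. The 20 endothelial and mural markers did not pass (median 0.20, adjusted p = 0.237), with Ly6a higher adjusted over the list alone. The 4 red blood cell markers did not pass (median -0.30, test higher, adjusted p = 0.503) but had an adjusted p of 5.13e-04 in the lower direction with the replicate block, and adjusted p = 0.312 with the block and an estimated correlation.

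Of the remaining lists, the 76 ribosomal protein genes rose (median 0.36, adjusted p = 1.37e-06, and adjusted p = 0.569 with an estimated correlation) with no member passing either way. D and E lay 1.49 and 1.42 above the other libraries in this list, and with the replicate block it fell (adjusted p = 0.0133, and adjusted p = 0.796 with the block and an estimated correlation). Without D and E the adjusted p of this list was 0.307, also in the lower direction. The 22 immediate early and dissociation stress genes rose (median 0.35, adjusted p = 0.00450, and adjusted p = 0.510 with an estimated correlation), and D and E lay 0.243 and 0.308 above the other libraries. The 18 axon injury genes rose (median 0.34, adjusted p = 0.0199, and adjusted p = 0.258 with an estimated correlation), with Gal, Tubb6 (0.83, SE 0.21), Stmn4 (0.70, SE 0.21) and Atf3 (0.69, SE 0.22) higher adjusted over the list alone. The 57 axon guidance and adhesion genes fell (median -0.20, adjusted p = 0.0199, and adjusted p = 0.559 with an estimated correlation), with Cntn5 (1.73, SE 0.40) higher adjusted over the list alone, and the call ended with the replicate block (adjusted p = 0.874). Sodium channels (adjusted p = 0.0723), calcium channels (0.340), TRP, ASIC and Piezo channels (0.0909) and purinergic genes (median -0.10, mean 0.00, adjusted p = 0.749) did not pass. Nor did GDNF family and neurotrophin genes (0.749), GABA, glycine and glutamate receptors (0.128), Y-linked genes (0.842), X-linked genes expressed from the inactive X (0.153) and mitochondrially encoded genes (0.658). With the replicate block the latter had an adjusted p of 2.76e-05 in the lower direction, and adjusted p = 0.312 with the block and an estimated correlation. The count of genes was 28 to 59 after leaving out any library but male L6S1 A, without which it was 129. It was 44, 29 and 45 without female L6S1 A, B and C, 46, 28 and 37 without female L345 A, B and C, 48, 29 and 28 without male L345 A, B and C, and 53, 59 and 53 without male L6S1 D, E and F. Leaving out 1 library ended the calls of Arap3, Cartpt, Cbln1, Esr1, Fbp1, Hoxb5, Hoxb6, Hoxc10, Htr3a, Kcnk2, Kcnk3 and Uts2b, and each library but male L6S1 A ended at least 1 of them. The highest adjusted p lay between 0.0669 for Htr3a (without male L345 C) and 0.159 for Kcnk2 (without female L345 B). The calls of 9 of the 17 lists ended without at least 1 library, with a highest adjusted p between 0.0703 for Hox groups 9 and 10 (without male L6S1 E) and 0.279 for the immune markers (without female L345 C).

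**Figure D4:**
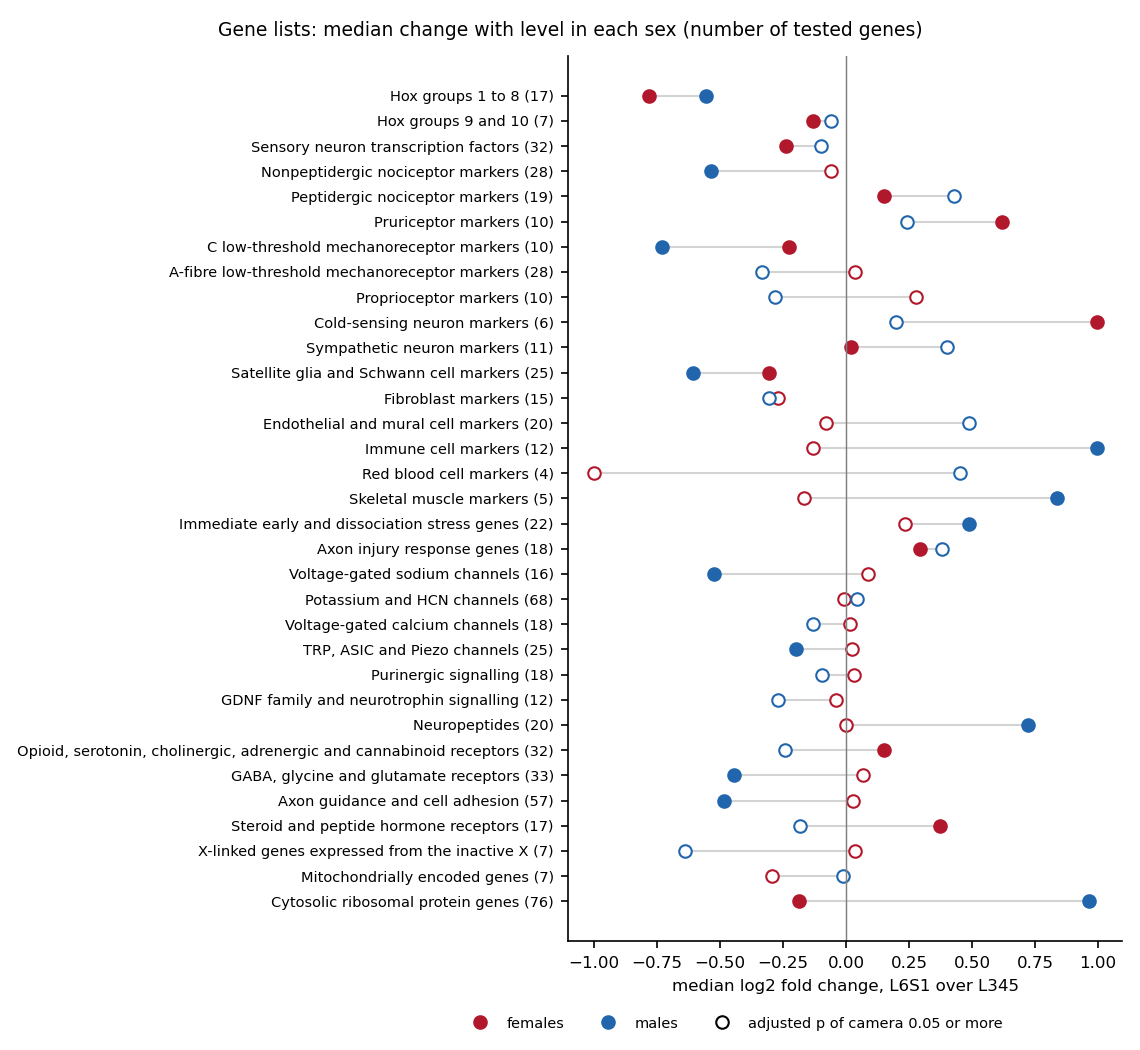
Points give the median log2 fold change of each gene list, L6S1 against L345, in females and in males, and filled points mark lists with a camera adjusted p under 0.05 at the preset correlation. Ribosomal protein genes lie at -0.19 in females and 0.97 in males.

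In females alone, the levels differed most in 3 genes that rose at L6S1. Hoxc11 rose by 4.49 (SE 0.54, adjusted p = 0.00620), Hotair by 4.20 (SE 0.59, adjusted p = 0.0165) and Chrna3 by 3.86 (SE 0.55, adjusted p = 0.0165), each in 3 of 3 libraries. Mrap2 (1.93, SE 0.33), an accessory protein of melanocortin receptors, and Negr1 (2.33, SE 0.40), an adhesion molecule, had the next smallest p and did not pass (adjusted p = 0.0567 for each). With the replicate block 56 genes passed, 51 higher and 5 lower, including these 3, Mrap2 (1.95, adjusted p = 0.00457) and Negr1 (2.31, adjusted p = 0.00142). That fit left only 2 residual degrees of freedom per gene, so its spread rests largely on what is shared between genes. More genes also passed in other fits, 42 higher and 5 lower by DESeq2, 31 and 3 without the low-count filter and 125 and 36 by limma voom. The markers of the sort and of the main cell types did not pass, among them Ret (-0.16), Mrgprd (-0.11) and Calca (-0.16), each at an adjusted p of 1.00.

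Of the lists in females, Hox groups 1 to 8 fell (median -0.78, adjusted p = 3.80e-16, and adjusted p = 0.00216 with an estimated correlation, but adjusted p = 0.491 with the block and an estimated correlation), with Hoxb5, Hoxb6 and Hoxb7 lower adjusted over the list alone. All 6 cold-sensing neuron markers had positive fold changes, and the list rose (median 1.00, adjusted p = 6.83e-07, and adjusted p = 0.0557 with an estimated correlation). Trpm8 went from 5.04 ± 2.17 to 16.3 ± 2.44 CPM (n = 3 and 3) and passed adjusted over the list alone, as did Penk. The opioid, serotonin, cholinergic, adrenergic and cannabinoid receptors rose (median 0.15, adjusted p = 6.83e-07, and adjusted p = 0.142 with an estimated correlation). Chrna3 was called, and Chrnb4 (2.63, SE 0.45), Htr3a (1.56, SE 0.39) and the cannabinoid receptor Cnr1 (1.39, SE 0.39) were also higher adjusted over the list alone. Steroid and peptide hormone receptors rose (median 0.37, adjusted p = 8.29e-04, and adjusted p = 0.142 with an estimated correlation), with Esr1 (2.12, SE 0.38, adjusted p over all genes 0.0594) higher adjusted over the list alone. Pruriceptor markers rose (median 0.62, adjusted p = 6.32e-05, and adjusted p = 0.142 with an estimated correlation) and glial markers fell (median -0.31, adjusted p = 2.87e-05, and adjusted p = 0.142 with an estimated correlation). Ribosomal protein genes fell (median -0.19, adjusted p = 0.00221, and adjusted p = 0.815 with an estimated correlation). Sensory transcription factors and C low-threshold mechanoreceptor markers also fell, with adjusted p of 0.00331 and 0.0322, and peptidergic markers, axon injury genes, Hox groups 9 and 10 and sympathetic markers rose, with adjusted p of 0.0351, 0.0139, 0.0256 and 0.00707. With an estimated correlation these 6 lists had adjusted p = 0.142 to 0.633. The replicate block ended the calls of Hox groups 9 and 10 (adjusted p = 0.126) and of sympathetic markers (0.0639) and added proprioceptor markers (0.0203, higher), red blood cell markers (0.00902, lower), immediate early genes (0.0132, higher) and mitochondrially encoded genes (0.00193, lower). With the block and an estimated correlation these 4 had adjusted p = 0.491 to 0.6555. Leaving out female L345 B ended all 3 gene calls (adjusted p = 0.109 for Hoxc11 and 0.287 for Hotair and Chrna3). The count was 1 without female L6S1 A or B and 2 without female L345 A or C, and it was 23 without male L6S1 D and E, which share the estimate of spread. The calls of 8 of the 13 lists ended without at least 1 of the 6 libraries, with a highest adjusted p between 0.0595 for glial markers (without female L6S1 A) and 0.426 for C low-threshold mechanoreceptor markers.

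In males alone, 34 genes passed and all were higher at L6S1 in this fit. Genes lower at L6S1 passed in other fits, 223 beside 742 higher by DESeq2, 35 beside 229 without a low-count filter and 4 beside 54 by limma voom. Hoxc11 went from 0.0248 ± 0.0430 CPM (n = 3, 1 count in all) to 2.45 ± 0.306 CPM (n = 4), with an adjusted p of 0.00105, and Hotair from 0.0649 ± 0.112 to 2.70 ± 1.04 CPM (adjusted p = 0.00560). Neuropeptide precursors rose, with Penk at 3.62 (SE 0.60, adjusted p = 0.0205), Cartpt at 2.24 (SE 0.40, adjusted p = 0.0315) and galanin (Gal) at 2.31 (SE 0.42, adjusted p = 0.0315), each in 4 of 4 libraries. Gal went from 202 ± 33.2 to 1002 ± 555 CPM, with 1418 and 1514 CPM in D and E and 371 and 703 CPM in A and F. Adm (3.51, SE 0.52, adjusted p = 0.0102), Gsta4 (3.31, SE 0.51, adjusted p = 0.0146), Srd5a2 (3.74, SE 0.68, adjusted p = 0.0315) and the vascular ligand Angpt4 (3.43, SE 0.63, adjusted p = 0.0315) also rose, in 4 of 4. So did Hoxd11 (3.17), Hoxd10 (2.96), Hoxd9 (2.15), Chrna3 (2.83), C1qb (2.66) and the endothelial surface antigen Ly6a (2.60, SE 0.45, adjusted p = 0.0253), all with adjusted p from 0.0147 to 0.0315 and in 4 of 4. Single markers such as Ret (-0.29, adjusted p = 0.503), Mrgprd (-0.74, 0.291) and Calca (1.08, 0.137) did not pass.

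Neuropeptides rose as a list in males (median 0.72, adjusted p = 2.94e-05), with 9 members higher and Cbln2 lower adjusted over the list alone, among them Tac1 (1.59, SE 0.42) and Calca. Ribosomal protein genes rose (median 0.97, adjusted p = 9.24e-13), 34 of 76 adjusted over the list alone. Immune markers rose (median 0.99, adjusted p = 0.0248), with C1qb called and 5 higher adjusted over the list alone, among them H2-Aa (1.78, SE 0.59) and H2-Ab1 (1.38, SE 0.45). Beside these rises, male L6S1 D and E lay 1.21 and 1.32 above the other libraries in neuropeptides, 1.49 and 1.42 in ribosomal protein genes and 1.42 and 1.64 in immune markers. Skeletal muscle markers (median 0.84, adjusted p = 0.0248) and immediate early genes (0.49, adjusted p = 0.0248) rose as well, and D and E lay 0.243 and 0.308 above the other libraries in immediate early genes. Lists that fell were Hox groups 1 to 8 (median -0.56, adjusted p = 0.0279), nonpeptidergic markers (-0.53, 0.00858), C low-threshold mechanoreceptor markers (-0.73, 0.0248), glial markers (-0.61, 0.0324) and sodium channels (-0.52, 0.0248). So did TRP, ASIC and Piezo channels (-0.20, 0.0284, and 0.9965 in the other direction without D and E), GABA, glycine and glutamate receptors (-0.44, 0.0248), axon guidance genes (-0.48, 0.00185) and Y-linked genes (-0.83, 0.0286). D and E lay -0.59 and -1.04 from the other libraries in nonpeptidergic markers and -0.94 and -1.26 in C low-threshold mechanoreceptor markers, and without them these lists had adjusted p of 0.138 and 0.115. With an estimated correlation none of these 14 lists passed, with adjusted p = 0.469 to 0.522. With the length and GC correction 8 lists passed. Leaving out male L6S1 A gave 3133 genes, 1619 higher and 1514 lower, while the count was 19, 18 and 28 without D, E and F, 11, 6 and 4 without male L345 A, B and C, 19 without D and E and 2 in a fit on these 7 libraries alone. All named calls but those of Hoxc11 and Hotair ended without at least 1 of male L345 A, B and C, with a highest adjusted p from 0.0877 for Adm to 0.236 for Srd5a2, Angpt4, C1qb and Gal. Without D and E the calls of Penk, Cartpt, Gal, Srd5a2, Angpt4, Hoxd10, Hoxd11, Ly6a and C1qb ended. Those of Adm, Gsta4, Chrna3, Hoxd9, Hoxc11 and Hotair held. The length and GC correction gave 33 genes, 23 of them among the 34, and ended the calls of Gal, Angpt4 and C1qb. In the fit on these 7 libraries alone Hoxc11 was the only named gene to hold its call, and Hotair had an adjusted p of 0.0804. In the lists, 8 calls ended without at least 1 of the 7 libraries, with a highest adjusted p from 0.0576 for sodium channels (without male L345 A) to 0.316 for glial markers (without male L6S1 A).

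The genes that passed in males mostly had the same direction in females, and no gene passed the test of a different response between the sexes in the edgeR fit with the low-count filter. Of the 34 male calls, 33 were higher and 1 lower in females, with a median log2 fold change of 2.63 in males and 1.42 in females, and 3 were called in both. Across all tested genes, which are not independent replicates, 50.1% were higher at L6S1 in females, and the effects of the sexes had a Pearson r of 0.03 and a Spearman rho of -0.14. The test of the difference by edgeR gave 0 genes, with 1805 at an unadjusted p under 0.05, and DESeq2 and limma voom also gave 0. Without the low-count filter edgeR gave 1 gene, Ly6a. The smallest p belonged to Ly6a (2.83, SE 0.62), Pls1 (-2.37, SE 0.52), Fabp4 (3.40, SE 0.78), Ly6e (2.39, SE 0.58) and Sema3d (-3.29, SE 0.81), each with an adjusted p of 0.409. Ly6a was 13.7 ± 2.85 and 11.7 ± 3.78 CPM at L345 and L6S1 in females and 8.21 ± 1.37 and 49.8 ± 33.7 CPM in males.

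By camera 13 lists differed between the sexes in their level effect, 6 with a more positive effect in males. These were ribosomal protein genes (median difference 1.19, adjusted p = 2.45e-14), neuropeptides (0.89, 4.81e-04), immune markers (0.98, 0.0331), endothelial markers (0.56, 0.0331), red blood cell markers (1.34, 0.0360) and skeletal muscle markers (1.25, 0.0274). The effect was more negative in males for axon guidance genes (-0.67, 4.81e-04), opioid and related receptors (-0.52, 0.00204) and GABA, glycine and glutamate receptors (-0.55, 0.00647). It was also more negative for nonpeptidergic markers (-0.36, 0.0262), sodium channels (-0.54, 0.0262), TRP, ASIC and Piezo channels (-0.32, 0.0262) and steroid and peptide hormone receptors (-0.77, 0.0282). None passed with an estimated correlation, with adjusted p = 0.574 to 0.662. With the length and GC correction 4 lists passed. In D and E ribosomal protein genes lay 1.49 and 1.42, neuropeptides 1.21 and 1.32, immune markers 1.42 and 1.64, endothelial markers 0.50 and 0.19 and nonpeptidergic markers -0.59 and -1.04 from the other libraries, and without D and E 4 of the 13 passed. Leaving out 1 library ended 8 of the 13 calls, with a highest adjusted p from 0.0508 for skeletal muscle markers (without male L345 B) and 0.0530 for sodium channels (without male L345 A) to 0.307 for nonpeptidergic markers.

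The comparison of males with females, averaged over the levels, showed the sex-linked genes and few others. Y-linked genes were high in males and near 0 in females. Eif2s3y was at least 19.9 CPM in males and at most 0.288 CPM in females (adjusted p = 1.61e-09), and Ddx3y at least 19.7 and at most 0.528 CPM (1.24e-06). Uty was at least 7.07 and at most 0.203 CPM (7.36e-07) and Kdm5d at least 3.87 and at most 0.144 CPM (3.32e-06). Xist (ENSMUSG00000086503, chromosome X, 103460375 to 103483217), the RNA that coats the inactive X chromosome, was at least 39.5 CPM in females and at most 0.536 CPM in males (log2 fold change -8.04, SE 0.56, adjusted p = 8.38e-07). Tsix, its antisense partner, overlaps it and held 30 counts.

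In all, 12 genes passed, 6 higher and 6 lower in males. Beyond Xist and the Y-linked genes, Pth2r (ENSMUSG00000025946, chromosome 1, 65282056 to 65389244), a receptor of the parathyroid hormone family of peptides, was lower in males (log2 fold change -2.69, SE 0.31, adjusted p = 5.14e-04). It was at 0.767 ± 0.174 CPM in male L345 and 0.503 ± 0.235 CPM in male L6S1 against 3.31 ± 1.52 and 4.88 ± 1.59 CPM in females. Chrdl1 (ENSMUSG00000031283, chromosome X, 143285674 to 143394262), an antagonist of bone morphogenetic proteins, was lower (-2.24, SE 0.32, adjusted p = 0.00731), as was the prokineticin receptor Prokr2 (-1.36, SE 0.24, adjusted p = 0.0377). All 3 were lower in 7 of 7 male libraries than in any female library. The other calls were Olfr558 and Npr3, lower in males, and Uba1y and Gm29650, higher, named after their values were seen and all low in counts. Uba1y and Gm29650 had 0 counts in females and 97 and 114 in males, the pattern of Y-linked genes, and are not calls beyond the sex-linked ones. Ret (-0.08, adjusted p = 0.911), Th (0.41, 0.665) and Apoe (0.58, 0.694) did not pass.

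Among the lists, the 4 Y-linked genes (adjusted p = 2.09e-27, and adjusted p = 0.00228 with an estimated correlation) were higher in males. The 7 X-linked genes expressed from the inactive X were lower (median -0.69, adjusted p = 4.28e-11, and adjusted p = 0.0109 with an estimated correlation), 6 of them adjusted over the list alone, among them Kdm6a (-1.07, SE 0.23) and Eif2s3x (-1.04, SE 0.26). Steroid and peptide hormone receptors were lower (median -0.38, adjusted p = 3.45e-04, and adjusted p = 0.156 with an estimated correlation), with Pgr (-1.41, SE 0.38) and Esr1 (-0.87, SE 0.25) lower adjusted over the list alone. Pruriceptor markers (median -0.30, adjusted p = 0.00191), opioid and related receptors (-0.19, 0.00983), GABA, glycine and glutamate receptors (-0.24, 0.00404) and axon guidance genes (-0.25, 9.10e-04) were lower and ribosomal protein genes (0.43, 4.28e-11) higher, with adjusted p = 0.471 to 0.772 with an estimated correlation. In ribosomal protein genes D and E lay 1.49 and 1.42 above the other libraries, and without them the adjusted p of this list was 0.728. The call of Prokr2 ended with 10 of the 13 omissions of a library, at most at an adjusted p of 0.232 without male L345 C, and that of opioid and related receptors without male L6S1 D (0.0675). The length and GC correction also ended the call of Prokr2. All females carry 1 form of label and males the other 2, and Chrdl1 had an adjusted p of 0.0702 without male L6S1 E and F and 0.0925 without D and E, in a range of 2.98e-07 to 0.0925 over all alternatives.

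**Figure D5:**
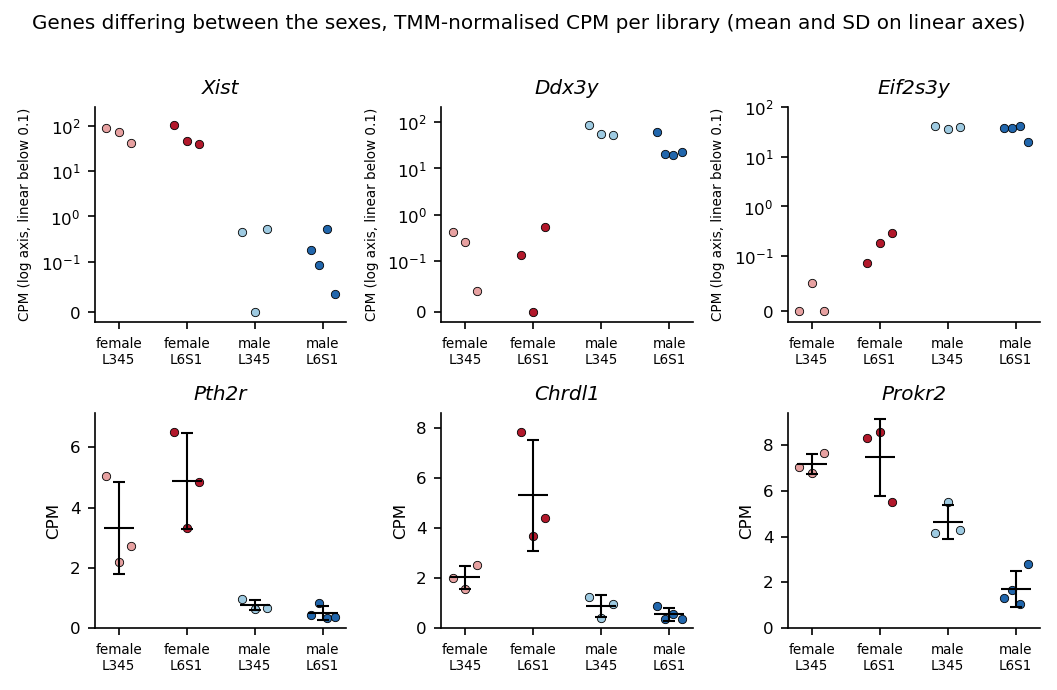
The plot shows CPM in each library by sex and spinal level of Xist, Ddx3y and Eif2s3y, on a log axis that is linear below 0.1, and of Pth2r, Chrdl1 and Prokr2 on a linear axis with bars for the mean and SD of 3 or 4 libraries. Pth2r, Chrdl1 and Prokr2 are lower in all 7 male libraries than in any female library.

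At L6S1, 13 genes differed between the sexes, 4 Y-linked genes higher and 9 genes lower in males, and 10 of the 13 were called in the average as well. The balance differed in other fits, with 765 higher and 516 lower by DESeq2, 95 and 102 without a low-count filter and 6 and 1 by limma voom. Pth2r (-3.27, SE 0.42, adjusted p = 0.00212), Chrdl1 (-3.25, SE 0.44, adjusted p = 0.00331) and Prokr2 (-2.10, SE 0.32, adjusted p = 0.0111) were lower. So were Pls1, an actin-bundling protein (-2.31, SE 0.35, adjusted p = 0.0106), Olfm3 (-2.39, SE 0.40, adjusted p = 0.0230) and the transmembrane collagen Col25a1 (-2.34, SE 0.39, adjusted p = 0.0258), all 6 in 4 of 4 male libraries. Pls1 was 12.0 ± 1.19 CPM in female L6S1 and 2.39 ± 1.23 CPM in male L6S1. Steroid and peptide hormone receptors were lower in males (median -0.87, adjusted p = 0.00139, and adjusted p = 0.292 with an estimated correlation), 6 of 17 adjusted over the list alone, among them Esr1 (-1.49, SE 0.34) and Nr3c2 (-1.08, SE 0.33). Axon guidance genes (median -0.60, adjusted p = 1.33e-04), GABA, glycine and glutamate receptors (-0.58, 0.00139), opioid and related receptors (-0.55, 0.00139), sodium channels (-0.40, 0.0315) and pruriceptor markers (-0.74, 0.0499) were lower in males. Neuropeptides (0.68, 0.00407) and ribosomal protein genes (1.04, 1.43e-14, 46 of 76 adjusted over the list alone) were higher. These 7 had adjusted p = 0.300 to 0.580 with an estimated correlation, Y-linked genes 0.0842 and X-linked genes (median -1.10, adjusted p = 5.11e-05) 0.143. Male L6S1 D and E lay 1.21 and 1.32 above the other libraries in neuropeptides and 1.49 and 1.42 in ribosomal protein genes, and without them 6 genes passed, while Olfm3 (adjusted p = 0.608), Pls1 (0.275), Prokr2 (0.271), Chrdl1 (0.215) and Col25a1 (0.215) did not. Limma voom ended 8 of the 13 calls, among them those of Xist (adjusted p = 0.0995), Pth2r, Chrdl1, Olfm3, Col25a1 and Prokr2, and without male L6S1 E and F the adjusted p of Pth2r was 0.126. With the length and GC correction 9 genes passed, and the calls of Olfm3, Col25a1, Pls1 and Prokr2 ended. Without male L6S1 A the count was 3149, 1554 higher and 1595 lower, and the calls of Col25a1, Olfm3 and Prokr2 ended without female L6S1 A (adjusted p = 0.331, 0.213 and 0.0810). Ended too were the calls of Pls1 without female L6S1 B (0.0536), of pruriceptor markers without male L6S1 F (0.118) and of sodium channels without male L6S1 E (0.105).

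At L345, the sexes differed in 5 genes, all sex-linked, 4 higher and 1 lower in males. Other fits gave 6 higher and 2 lower by DESeq2 and without the low-count filter, and 6 and 7 by limma voom. Eif2s3y was 39.5 ± 2.42 CPM in males (n = 3) and had 1 count in the 3 female libraries together, and Kdm5d was at least 183-fold higher in males against a floor of 3 counts over the female group, which held none. With Ddx3y (adjusted p = 1.18e-04) and Uty (5.53e-05) these were higher, and Xist was lower (-7.72, SE 0.81, adjusted p = 1.65e-04). Ret (-0.01), Gfra1 (0.34), Mrgprd (0.30) and Calca (-0.37) had adjusted p of 1.00. Y-linked genes (adjusted p = 1.95e-66, and adjusted p = 6.22e-05 with an estimated correlation) were higher and X-linked genes expressed from the inactive X (median -0.60, adjusted p = 1.51e-12, and adjusted p = 0.00673 with an estimated correlation) lower in males. Endothelial and mural markers (median -0.44, adjusted p = 1.73e-05), peptidergic markers (-0.18, 0.00256), neuropeptides (-0.36, 0.00256) and red blood cell markers (-0.32, 0.00256) were lower in males. So were pruriceptor markers (-0.33, 0.0165), skeletal muscle markers (-0.45, 0.0191), mitochondrially encoded genes (-0.44, 0.0388) and ribosomal protein genes (-0.14, 0.0165). Nonpeptidergic (0.19, 0.00157) and A-fibre mechanoreceptor markers (0.15, 0.0191) were higher, and in these 10 lists no member was called over all genes. With an estimated correlation these 10 had adjusted p = 0.108 to 0.939, and with the replicate block red blood cell markers lost their call (0.0743) and immediate early genes gained one (0.0488, lower, and adjusted p = 0.790 with the block and an estimated correlation). Without female L345 A 4 lists passed, and nonpeptidergic markers (adjusted p = 0.761) and mitochondrially encoded genes (0.648) had the other direction. Calls that ended over all omissions reached adjusted p of 0.151 (skeletal muscle, without male L345 B) to 0.968 (ribosomal protein genes, without female L345 A).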

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

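The tests of autonomic genes (in the set of 4 given), of partner transcripts, of gene length and GC content, and of the difference between peptidergic and nonpeptidergic markers were chosen after the result was seen. Named genes and, per library, the total count, the share of the highest genes and the mitochondrial share were tested for a library apart in male L6S1. Of these 57 values, 6 were found, all of genes, and chance alone gives about 1 in 20. The rule looks for a single library apart, so it cannot flag D and E as a pair. Hoxd10 was 90.3 CPM in replicate A against 53.8 to 59.9 in the rest. Chrnb4 was 57.7 CPM in F against 16.6 to 21.5. Apoe was 4988 CPM in E against 690 to 1343. Eif2s3y was 19.9 CPM in F against 38.3 to 41.1. Ddx3y was 61.2 CPM in A against 19.7 to 22.3. Col25a1 was 1.29 CPM in E against 0.668 to 0.707.

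The level effect of 13 gene lists differed between males and females by camera. The adjusted p was 2.45e-14 for ribosomal protein genes, 4.81e-04 for neuropeptides, 4.81e-04 for axon guidance genes and 0.00204 for opioid, serotonin, cholinergic, adrenergic and cannabinoid receptors. It was 0.00647 for GABA, glycine and glutamate receptors, 0.0262 each for nonpeptidergic markers, sodium channels and TRP, ASIC and Piezo channels, and 0.0274 for skeletal muscle markers. It was 0.0282 for steroid and peptide hormone receptors, 0.0331 each for endothelial and immune markers and 0.0360 for red blood cell markers. With an estimated correlation these had adjusted p = 0.574 to 0.662.

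Chrna3 and Chrnb4 were higher at L6S1, and autonomic ganglion neurons in these pools could bring such transcripts. The summed CPM of Phox2a, Hand2, Dbh and Slc6a2, which autonomic neurons also express, rose by at most 0.00729 of the rise of Chrna3, from 0.0798 to 0.279 CPM in males, and fell in females. That argues against autonomic neurons as the source. A difference between spinal levels in the Ret-positive neurons themselves stays open and was not tested.

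C1qb, Trac, Igha and Blnk, genes of immune cells, were higher at L6S1. For C1qb, Trac and Igha, transcripts that the same cells carry (C1qa and C1qc, Cd3d, Cd3e and Cd3g, Igkc and Jchain) rose by at most 0.0192 of the rise of the gene, which argues against macrophages, T cells or plasma cells. For Blnk, more immune cells stay open. The median log2 fold change of 11 other immune markers was 0.18 (0.1788, SE of the mean 0.201), with 8 of 11 higher. It was 0.87 in males (SE 0.208, 10 of 11 higher) and -0.14 in females (SE 0.378, 3 of 11 higher), so that more immune cells in the male pools alone are not excluded. A difference between spinal levels was not tested apart from these.

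Male L6S1 D and E lay apart from the other 11 libraries on the first component. Across genes, their deviation from the mean of all libraries had a Spearman rho with gene length of -0.473 in D and -0.525 in E. In the other 11 it was -0.0492 to 0.358. With GC content the rho was 0.331 and 0.205, within the range of the other 11, -0.664 to 0.684. After a correction for gene length and GC content the smaller of the 2 gaps was 5.24 SDs, which argues against such a bias as the whole cause. Glia, fibroblasts, vessel or immune cells stay open, since the lowest of their 4 lists, that of glia, lay at most 0.236 higher on the log2 scale in D or E. Immune markers lay 1.42 and 1.64 higher in D and E, fibroblast markers 0.311 and 0.524, and endothelial and mural markers 0.503 and 0.193. The test took the 4 lists together, so it does not judge any single cell type. A lower share of nonpeptidergic neurons also stays open. Peptidergic exceeded nonpeptidergic markers by at least 0.5697 in both, but the peptidergic median itself was 0.348 in E and not higher in D, at -0.0213. The design gives no biological group that separates D and E from A and F, so no biological explanation beyond these shares of cells was tested.

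Other splits of the libraries into groups of the same sizes were fitted in the same way. For the levels averaged over the sexes, 4 of 100 drawn splits, the real one included, gave at least the real 69 genes, and the highest other gave 2482. This share is just under 0.05 and rests on drawn splits, so it does not exclude chance. The 3 others with as many genes all put male L6S1 D, E and F on one side and A on the other, a structure of the samples. Of the 21 other splits that part as many letter pairs as the real one, the highest gave 2 genes. For the sexes averaged over the levels the share was also 4 of 100, with 12 real genes and a highest other of 967, which does not exclude chance either. Of the 3 others with as many genes, 2 parted male L6S1 A from D, E and F. The 12 include the Y-linked genes and Xist, which part the sexes by themselves, so the count does not bear on the other calls. The share was not under 0.05, and chance is not excluded, for the levels in males (2 of 35 splits, 34 real genes, highest other 4052). The same holds for the sexes at L6S1 (2 of 35, 13 real genes, highest other 3978). For the difference of the level effect the splits decide nothing, since with 0 real genes by edgeR (1805 at an unadjusted p under 0.05, and 0 by DESeq2 and limma voom) all 100 of 100 have at least as many. The highest other there was 393. In males and at L6S1 the other split again parted A from D, E and F. For females and for the sexes at L345, 1 of 10 splits gave as many, and the splits are too few for a share under 0.05, with 3 and 5 real genes and a highest other of 0 in both. With the female replicate letters taken as pairs, of the 3 other splits that part as many pairs the highest gave 0 genes.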

How the results depend on the processing

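The corrections for length and GC content, the omission of male L6S1 D and E together, the blocks with that correction or for lists, and the omission of single libraries for lists were chosen after seeing the data. The cause was not tested for the changes below unless fewer samples or another set of genes is their construction. Gene counts in the order levels averaged, females, males, sexes averaged, sexes at L6S1 and at L345 were 187, 47, 965, 24, 1281 and 8 by DESeq2, which also replaced the low-count filter by its own and had 26884 genes. Without a low-count filter they were 144, 34, 264, 19, 197 and 8, and 1 for the difference of the level effect. By limma voom the levels gave 314, 161 and 58, the sexes 7 at L6S1 and 13 at L345. With the replicate block females gave 56, and with that block and the length and GC correction the levels gave 160 and females 93. The correction alone gave 99 for the levels, 18 in females, 33 in males, 11 for the sexes, 9 at L6S1 and 5 at L345. A fit on the 2 groups alone gave 14 in females and 2 in males. Without male L6S1 E and F the levels gave 37 and males 9, and the sexes at L6S1 7. Without D and E females gave 23, males 19, the sexes 7 and the sexes at L6S1 6. Omitting 1 library gave 28 to 129 for the levels, 0 (without female L345 B, by edgeR) to 3 in females, 4 to 3133 in males. It gave 10 to 14 for the sexes, 9 to 3149 at L6S1, 5 to 5 at L345 and 0 to 0 for the difference. Lists called, in the order levels, females, males, difference, sexes, L6S1, L345, were 17, 13, 14, 13, 8, 10 and 12. They were 1, 1, 0, 0, 2, 0 and 2 with an estimated correlation, and 3, 1, 4, 0, 2, 4 and 1 by fry. The correction for length and GC content gave 11, 8 in males and 4 for the difference, and omitting D and E 8 in males and 4 for the difference. A block with an estimated correlation gave 0, 0 in females and 2 at L345. Omitting 1 library gave 13 to 19, 11 to 15, 9 to 15, 9 to 16, 7 to 11, 8 to 14 and 4 to 14 lists. In the other direction went, for the levels averaged, ribosomal protein genes (adjusted p = 0.307 without D and E, 0.0133 with the block, 0.796 with the block and an estimated correlation). So did red blood cell markers (5.13e-04 with the block), immune markers (0.621 and 0.796 with the block and with both) and skeletal muscle markers (0.722 and 0.865), and in males TRP, ASIC and Piezo channels (0.9965 without D and E). For the sexes averaged so did immediate early genes (0.00682 with the length and GC correction) and nonpeptidergic markers (0.00838 without D and E), and at L6S1 mitochondrially encoded genes (0.0392 without D and E). At L345 so did, without female L345 A, nonpeptidergic markers (0.761, from 1.84e-05 over omissions) and mitochondrially encoded genes (0.648, from 0.00125). Of 2821 other values of named genes 2539 kept their side of the threshold (93 of them uncalled and with another sign), 257 lost and 25 gained a call and 0 changed direction with a call. Of 3332 of lists these were 2841 (271), 387, 90 and 14. The block changed no call of a list beyond those given in the report. The block was fitted for the levels averaged over the sexes (90 genes), for females and for the sexes at L345. A block fit of the male levels, which share only the letter A, was not run. The sexes averaged, the sexes at L6S1 and the difference of the level effect were not fitted with the block. Depth limits the lowest genes, such as Hoxc11 with 1 count in male L345.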
